A study of Mus musculus with 3 samples.

How the data were processed

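RNA was sequenced from T-helper 1 cells of C57BL/6NJ mice, primary CD4-lineage T cells differentiated in culture, in 3 libraries of a single group. The labels call them biological replicates 1, 2 and 3, each with 1 technical replicate and a biosample of its own, and give the same donor entry for all 3. They do not say whether the cells came from separate animals or cultures, so p-values between libraries measure only the spread between these samples, which may be technical in part. The assay is labelled total RNA sequencing, while the library protocol named in the labels is for polyA-selected RNA. Which kit was used, and whether it marks strand, is not given in the sources used here.

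The deposited values are raw counts of read pairs per gene. Per the file headers, the authors made these counts with featureCounts 1.4.6-p4 on exons grouped by gene, from GENCODE release M13 gene models, counting pairs with both ends aligned and with strand option 1, on mm10 per the labels. The name of the alignment in the header carries the word star2, and the aligner's version is not given in the sources used here. The headers also carry 24 hr and replicate numbers that match those of the labels. The gene length used here is the exon length in the same deposited files. Each file lists 50600 genes.

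TPM, FPKM and CPM (counts scaled to library size) were computed here from the deposited counts and exon lengths, because the tests had been chosen for TPM. Posterior mean TPM could not be made from counts and was not run. The tests, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Symbols and biotypes were taken from GENCODE release M21 by gene identifier, which matched 50376 identifiers and left 224 without a symbol. Coordinates are those of the deposited files. From the exon coordinates, each gene was placed in 1 of 4 classes: overlapped (an exon shares bases with an exon of a gene on the opposite strand), spanned (inside the span of an opposite-strand gene without shared exon bases), near (an opposite-strand gene within 5000 bases) and isolated (none of these). This classification and every value that uses it were added afterwards. Values of overlapped genes are uncertain, because the strand option decides which gene of a pair receives the read pairs. Values of the other classes, isolated genes included, are uncertain too. If the option was set against the strand of the library, their counts would be only a residue of their own mRNA.

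Total counts were 3553547, 2945353 and 3369468 in replicates 1, 2 and 3. A count of 0 allows up to 3 counts, which is 0.844, 1.019 and 0.89 CPM in replicates 1, 2 and 3. Intervals and these floors cover counting error only, since read pairs without molecular identifiers are not independent molecules.

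There is 1 group, so genes were compared within libraries and libraries with each other. The fixed gene lists were 40 with 629 entries, of which 4 had no match in the annotation. They comprise 5 lineage lists (Th1, Th2, Th17, Treg and Tfh), 10 of T cell state, 11 of metabolic, cell cycle and stress programs, 2 that describe the libraries (sex-linked genes, and abundant nuclear and small noncoding RNA) and 12 for other cell types. The ratio of Tbx21 to Gata3, Foxp3 and Bcl6 was taken as log2((TPM + 1)/(TPM + 1)) within a library. Lineage lists were compared by the difference in median log2(TPM + 1), with a two-sided permutation test of gene labels (100000 resamples, exact where a list had fewer than 10 members) and Benjamini-Hochberg adjustment over 4 comparisons. The median of each list with 5 or more members was placed among 10000 random lists of the same size from 21764 protein-coding genes. A gene counted as detected at 1 TPM or more in every library.

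Variation between libraries was tested per gene with a chi-square test against Poisson counting error (2 degrees of freedom) at library sizes scaled by TMM, over genes that passed edgeR's filterByExpr, with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was the square root of edgeR's common dispersion with an intercept-only design. For each list, the SD over libraries of its mean log2 CPM (prior count 2) was compared with 10000 random lists matched on level in 20 bins. Receptor segment shares have exact binomial 95% intervals. The chi-square test was tested on simulated counts for 10216 genes. Of 200 changed genes it recovered 13.5% at 1.25-fold, 40% at 1.5-fold and 75% at 2-fold, with 0, 6 and 8 false calls. The simulated counts had Poisson error only, at known library sizes, without TMM scaling or a shift shared by a class of genes. The numbers of false calls therefore do not apply to data with such a shift. Software was R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

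The rule for named genes takes Tbx21, Gata3, Foxp3, Bcl6, Ifng, Stat4, Il4 and Il17a; the 4 members of each list with the highest mean TPM (3 for other cell types) and the 2 lowest of each lineage list; the 20 protein-coding genes with the highest mean TPM outside mitochondrial and ribosomal protein genes; the 15 protein-coding genes with the largest ratio between libraries among those past the test with a mean of 10 TPM or more; receptor segments above 5% of their locus; and the sex-linked list. Some genes that the rule takes are not reported here. The text names members of this set, and other genes are said to have been chosen after their values were seen. Alternatives covered the pseudocount, unit, centre, background, threshold, normalization, filter and each library left out.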

Results

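The data are gene counts from 3 RNA-seq libraries of mouse T-helper 1 (Th1) cells, the CD4 T cell lineage known for the transcription factor T-bet and for interferon gamma. No other cell type or condition was measured, so the questions the design allows are which genes of this and other T cell lineages were counted, which gene programs were counted, and how far the replicates differed. Total counts were 3553547, 2945353 and 3369468 in replicates 1, 2 and 3, and 16481, 16172 and 16615 genes had at least 1 count. Levels are mean TPM ± SD over the 3 libraries (n = 3) unless counts are given, and counts are listed in the order of replicates 1, 2 and 3.

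The highest counts were mostly on genes whose exons overlap those of a gene on the opposite strand. Phykpl, a lyase gene (ENSMUSG00000020359, mm10 chromosome 11, 51584757 to 51604489), had the most counts of any protein-coding gene, at 56428, 60038 and 57038, and its exons overlap Hnrnpab on the other strand. Gm20721 (ENSMUSG00000090625, opposite Gnas, which encodes a G protein subunit) stood at 10100 ± 478 TPM, Tlcd1 (opposite Rpl23a) at 2530 ± 153 and Wdr38 (opposite Rpl35) at 2260 ± 159. Of the 20 protein-coding genes with the highest TPM outside mitochondrial and ribosomal protein genes, 16 overlapped an opposite-strand exon. The 2 isolated ones were Npm1, a nucleolar chaperone gene, at 1850 ± 344 TPM and Ptma, which encodes prothymosin alpha, at 1670 ± 384 TPM. Hsp90ab1 (2470 ± 405 TPM) and Eef1a1 (2050 ± 463 TPM), a chaperone and a translation factor gene, had an opposite-strand gene nearby without overlap.

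Genes that overlap an opposite-strand exon were 16.2% of the annotated genes and held 71.9% ± 4.97 of the counts, while isolated genes were 53.5% of the genes and held 12.2% ± 2.37. Among the 100 genes with the highest mean counts, 93 were overlapped, against 42.4% of the other 10066 genes with 10 counts or more in every library (two-sided Fisher's exact test across genes, p = 1.3e-26). In the mitochondrial genome, mt-Nd6 (mm10 chromosome M, 13552 to 14070, opposite mt-Nd5 and the only mRNA gene on its strand) had 46100 ± 6560 counts per kb. The highest of the other 12 mitochondrial mRNAs had 2490 ± 366, so that mt-Nd6 was 15.1, 23.3 and 18.2 times as high in the 3 libraries, and 6 of the 12 had 3 counts or fewer in every library. By biotype, antisense genes took 16.7% ± 1.68 of the counts. For every overlapped gene named here, the count on the gene's annotated strand therefore cannot be assigned to that gene alone. The opposite gene is named beside it. Counts on isolated and other genes without such an overlap may be only a residue of their mRNA, so they are not a cleaner measure.

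**Figure D1:**
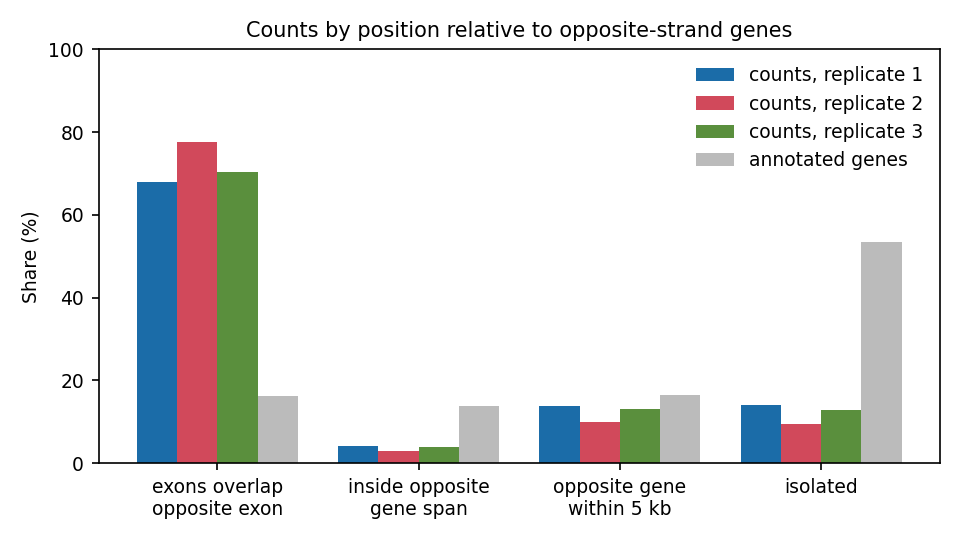
Bars give the share, in percent, of each library's counts (colours, replicates 1 to 3) and of the annotated genes (grey) in each of 4 classes of position relative to genes on the opposite strand. Overlapped genes, 16.2% of the genes, held 68.0%, 77.5% and 70.3% of the counts in replicates 1, 2 and 3.

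Counts on the gene of T-bet, the Th1 factor, were few. Tbx21 (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331) had 15, 11 and 8 counts, or 2.47 ± 0.727 TPM, and Ifng, which encodes interferon gamma, had 2, 2 and 1 counts, at or under the 3 counts that a count of 0 allows. Gata3, the Th2 factor, stood at 4.49 ± 0.97 TPM (opposite Gm13256), and Bcl6, the Tfh factor, at 0.454 ± 0.187 TPM (opposite Gm37419). Foxp3, the regulatory T cell factor, stood at 120 ± 1.67 TPM with 900, 829 and 907 counts, and its exons overlap Ccdc22 on the opposite strand. Stat4, which transmits interleukin 12 signals, had 5.01 ± 1.87 TPM, Il4 had 3.88 ± 1.28 TPM and Il17a had 0 counts in each library. As log2 ratios, Tbx21 was at -0.67 ± 0.39 relative to Gata3 and -5.14 ± 0.33 relative to Foxp3, lower in 3 of 3 libraries each time, and at 1.24 ± 0.32 relative to Bcl6, higher in 3 of 3. An exact sign-flip test with 3 libraries cannot go below p = 0.25, so none of these was tested across libraries. All 3 comparison factors are overlapped genes and Tbx21 is not, so the ratios compare counts of unlike position. If the strand option was set against the library, the counts on Tbx21 and Ifng would be only a residue of their mRNA. Those on Foxp3 may then be of Ccdc22. These counts thus do not show that the cells lacked Tbx21 or Ifng mRNA, or that they carried Foxp3 mRNA.

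The 4 Th1 list members with the highest TPM were cytokine and chemokine genes. Lta (lymphotoxin alpha) stood at 234 ± 54.8 TPM, Tnf at 108 ± 35.9, and the chemokine genes Ccl4 and Ccl3 at 94.5 ± 31.6 and 73.2 ± 24.4, none of them overlapped. Of the 26 Th1 members 14 were detected in every library, and Hlx and Havcr2 had 0 counts in each. The Th2 list had 10 of 20 members detected, led by Ptgdr2 at 53.3 ± 3.56 TPM (opposite Ccdc86) and Stat6 at 50.7 ± 6.86 TPM (opposite Nab2), with Ccr3 and Areg at 0. The Th17 list had 6 of 18 detected, with Hif1a at 21.7 ± 5.73 TPM (opposite Gm15283) and Nfkbiz at 5.7 ± 1.81 TPM, and Rorb and Ltb4r1 at 0. The Treg list had 12 of 18 detected: besides Foxp3, Tnfrsf4, which encodes the costimulatory receptor OX40, stood at 165 ± 70.3 TPM and Il2ra, which encodes the interleukin 2 receptor alpha chain, at 61.8 ± 13.8 TPM, while Entpd1 and Itgb8 were at 0. The Tfh list had 9 of 15 detected, with Cd200 at 69.5 ± 21.6 TPM. The inhibitory receptor genes Pdcd1 and Btla stood at 49.8 ± 19.1 and 44.3 ± 17.8 TPM, and Ascl2 and Cebpa (opposite Gm45091) at 0.

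No difference in median level between the Th1 list and another lineage list passed the test. The median TPM was 3.41 ± 0.606 for Th1, 1.74 ± 0.091 for Th2, 0.111 ± 0.067 for Th17, 6.13 ± 0.692 for Treg and 3.73 ± 1.29 for Tfh, and over isolated members 0.73 ± 0.38, 0.165 ± 0.0741, 0.028 ± 0.0486, 6.93 ± 0.633 and 3.73 ± 1.29. On the log2(TPM + 1) scale the Th1 median minus the other was 0.71 ± 0.238 for Th2 (permutation test, adjusted p = 0.822), 1.98 ± 0.272 for Th17 (permutation test, p = 0.0278, adjusted p = 0.111), -0.70 ± 0.289 for Treg (permutation test, adjusted p = 0.822) and -0.07 ± 0.232 for Tfh (permutation test, adjusted p = 0.963). The genes permuted are not independent replicates. The Th1 median was the higher in 3 of 3 libraries against Th2 and Th17, and the lower in 3 of 3 against Treg. With a pseudocount of 0.1 the Th17 difference passed (permutation test, adjusted p = 0.0141, with a range of 0.0141 to 0.948 over the alternatives), and among members at 1 TPM or more in at least 1 library it was -0.06, while the Th2 difference there was -0.60. Over the alternatives the Treg difference ranged from -2.22 to -0.39 and the Tfh difference from -1.94 to 0.08, none of them past the test. Among random protein-coding lists the medians lay at percentile 96.1 for Th1, 82 for Th2, 29.3 for Th17, 99 for Treg and 92.6 for Tfh, or 91.7, 76.3, 73, 99 and 96.6 for their isolated members among isolated genes, a comparison added after the values were seen. Against detected protein-coding genes only, the percentiles were 0 for Th1, Th2 and Th17, 8.8 for Treg and 0.3 for Tfh. Here and below, that background leaves out undetected genes while the lists keep theirs. A list with many undetected members therefore falls low by construction.

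Lists of T cell identity and early activation stood at the top of the state lists. All 20 T cell identity genes were detected, with a median of 65.8 ± 14.5 TPM at percentile 100. The receptor constant genes Trac and Trbc2, both isolated, stood at 196 ± 73.4 and 117 ± 35.2 TPM, Cd5 at 110 ± 27.1 and Cd247 at 185 ± 5.54 TPM (opposite Pou2f1). Early activation genes were detected for 18 of 20 members (median 28 ± 10.3 TPM, percentile 100), led by Il2, which encodes the T cell growth factor, at 265 ± 118 TPM, Junb at 171 ± 22.2 (opposite Prdx2), Myc at 102 ± 26.7 and Cd40lg, which encodes the ligand of CD40, at 95 ± 30.8. Of the cytokine list 14 of 31 members were detected (median 1.69 ± 1.44 TPM, percentile 82.4), with Il2, Lta and Tnf joined by Mif at 225 ± 87.8 TPM. That median rested much on replicate 3, with log2(TPM + 1) medians of 1.004, 0.778 and 2.119, and the percentile was 69.3 without replicate 3, 99.7 with means in place of medians and 99.5 among isolated genes. Cytokine receptors had 18 of 21 detected (6.43 ± 2.15 TPM, percentile 99.3), with Il2rb at 36.8 ± 11.6 TPM and Il21r at 29 ± 6.63 TPM. Among STAT and JAK genes 14 of 15 were detected (13.2 ± 3.94 TPM, percentile 99.9), and Jak2 stood at 28.2 ± 11.4 TPM and Stat5b at 17.2 ± 4.33 TPM. Against detected protein-coding genes only, the percentile was 0 for cytokines, 8.5 for cytokine receptors and 75.8 for STAT and JAK genes, so that neither of the last was still in the highest 2.5%.

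The other state lists ranged from percentile 40.8 to 98.4. The naive and central memory list had 10 of 12 members detected (8.39 ± 2.44 TPM, percentile 98.4), with Tcf7, a factor of naive T cells, at 105 ± 23.7 TPM and the homing receptor gene Ccr7 at 48.9 ± 8.63 TPM. Inhibitory receptors had 8 of 12 detected (8.37 ± 1.28 TPM, percentile 98.4), among them Ctla4 at 28.5 ± 8.73 TPM and Cd274 at 25.6 ± 6.25 TPM. Chemokine receptors had 7 of 18 detected (0.366 ± 0.0786 TPM, percentile 47.2), with Ccr4 at 11.4 ± 1.73 TPM, Ccr8 at 9.83 ± 1.39 and Cxcr6 at 3.94 ± 0.386. The cytotoxic granule list had 5 of 16 detected (0.26 ± 0.0693 TPM, percentile 40.8), led by Lamp1 at 28.2 ± 9.18 TPM (opposite Grtp1) and Srgn at 25.6 ± 8.13 TPM, and Fasl stood at 4.57 ± 0.53 TPM. Interferon response genes had 10 of 25 detected (0.823 ± 0.13 TPM, percentile 66.8), with the isolated GTPase gene Igtp at 15.1 ± 5.15 TPM and the immunoproteasome genes Psmb9 (opposite Tap1) and Psmb8 (opposite Gm20496) at 52.8 ± 1.57 and 49 ± 13.4 TPM. Neither the naive and central memory list nor the inhibitory receptors stayed in the highest 2.5% against detected protein-coding genes, where their percentiles were 30.8 and 32.6, and chemokine receptors, the cytotoxic granule list and interferon response genes were then at 0. The naive and central memory list was at percentile 93.1 among isolated genes, with an isolated median of 3.09 ± 0.731 TPM, and the inhibitory receptors at 95.2 with means in place of medians.

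Cell cycle, glycolytic and respiratory genes stood among the highest lists. All 20 S phase genes were detected (75.5 ± 19.5 TPM, percentile 100), including the replication clamp gene Pcna at 193 ± 61.5 TPM, the helicase gene Mcm3 at 130 ± 36 and Rrm2, a subunit of ribonucleotide reductase, at 98.8 ± 45.8. All 20 G2 and M phase genes were detected (32.2 ± 8.01 TPM, percentile 100), with Mki67 at 117 ± 21.2 TPM, Top2a at 94.5 ± 27 and Ccna2, which encodes cyclin A2, at 237 ± 10.4 (opposite Exosc9). Glycolysis had 17 of 18 members detected (46.9 ± 11.6 TPM, percentile 100), with the isolated genes Ldha and Pkm at 405 ± 126 and 225 ± 59.5 TPM. All 24 nuclear oxidative phosphorylation genes were detected (46.7 ± 11.2 TPM, percentile 100), and the ATP synthase genes Atp5b and Atp5a1 stood at 238 ± 78.4 and 194 ± 57.6 TPM. Of the 13 mitochondrial mRNAs 7 were detected (763 ± 215 TPM, percentile 100) and 5 had 0 counts in every library. The highest was mt-Nd6 at 25200 ± 4160 TPM (opposite mt-Nd5), and mt-Nd4 and mt-Nd1 were both at 1060 TPM (SD 218 and 358). With the strand option set against the library, mt-Nd6 would read the other strand and the rest would be a residue. The level of this list is then not a measure of its mRNAs.

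The remaining programs concern stress and biosynthesis. The ATF4 and amino acid list had 11 of 16 members detected (37.4 ± 12.6 TPM, percentile 100), with Atf4 itself at 165 ± 42.5 TPM and Ddit3 at 196 ± 19.8 TPM (opposite Mars), but the median of its 4 isolated members was 1.08 ± 0.693 TPM and 1 of them was detected. The unfolded protein response list had 12 of 14 detected (34.2 ± 10.1 TPM, percentile 100), with the chaperone genes Calr and Hspa5 at 375 ± 70.4 and 156 ± 44.3 TPM. Heat shock genes had 9 of 12 detected (42.6 ± 9.62 TPM, percentile 100), with Hspa8 at 488 ± 110 TPM and Hsp90aa1 at 416 ± 102, but the median of its 5 isolated members was 2.88 ± 0.884 TPM and 3 of them were detected. Cholesterol synthesis had all 18 detected (11.2 ± 2.31 TPM, percentile 99.9), with Srebf2, its transcriptional regulator, at 30 ± 10.6 TPM and Hmgcs1 at 27.7 ± 9.77. Targets of p53 had 12 of 14 detected (8.55 ± 1.97 TPM, percentile 99.2), with Ccng1 at 65.5 ± 27.7 TPM and Cdkn1a, which encodes the p21 cell cycle inhibitor, at 56 ± 18.2. The hypoxia list had 11 of 15 detected (3.51 ± 0.694 TPM, percentile 92), with Ddit4 at 16.6 ± 8.05 TPM. In all, 17 of 39 lists lay in the highest 2.5% of random lists, and against detected protein-coding genes as background 10 did. Cholesterol synthesis was then at percentile 64.4, p53 targets at 34.6 and hypoxia at 0.2, and among isolated genes heat shock was at 92.5.

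**Figure D2:**
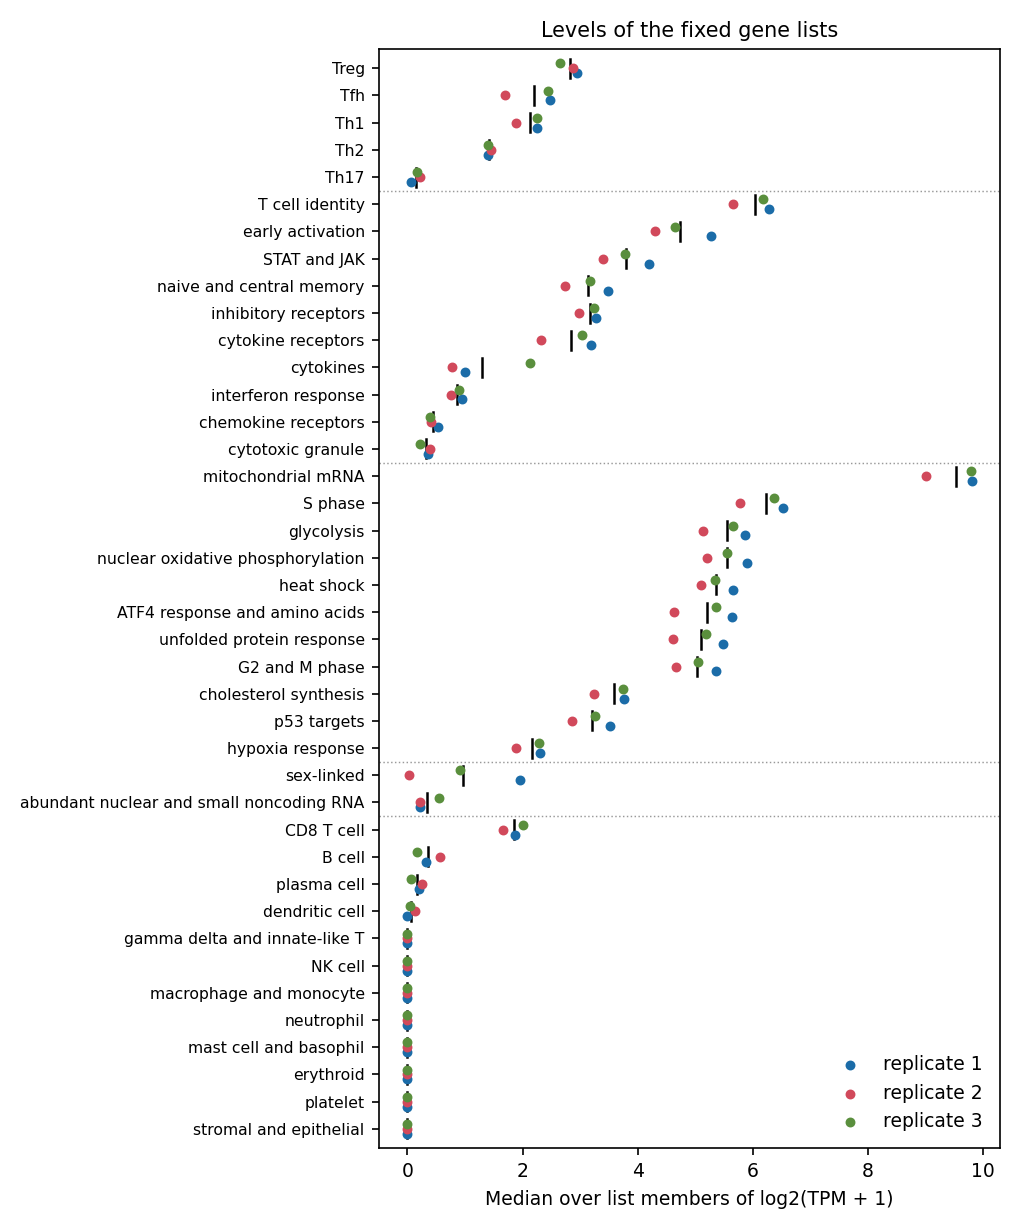
Points give, for each library (colours), the median over the members of each fixed gene list of log2(TPM + 1), and black ticks give the mean of the 3 libraries; dotted lines part lineage, state, program, library and other cell lists. T cell identity, cell cycle and metabolic lists stand to the right, while 8 of the 12 other cell lists have a median of 0 in every library.

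Markers of other cell types had few counts, which does not show that these cells were absent. If the strand option was set against the library, counts on genes without an opposite-strand overlap would be only a residue of their mRNA. Of 131 measured members of the 12 lists 83 had 0 counts in every library and 18 were detected, and 8 lists had a median of 0 TPM: gamma delta and innate-like T cells (percentile 13.9), NK cells (12.3), macrophages and monocytes (7.9), neutrophils (8.5), mast cells and basophils (8.7), erythroid cells (13.9), platelets (8.7), and stromal and epithelial cells (8.4). The medians were 0.285 ± 0.177 TPM for B cells (percentile 40.4), 0.134 ± 0.0796 for plasma cells (30.9) and 0.0421 ± 0.0484 for dendritic cells (23), and 5.3 ± 1.32 TPM for the 2 genes of CD8 T cells. The exceptions above 40 TPM were Csf1r, a macrophage receptor gene, at 160 ± 6.06 TPM (opposite Hmgxb3), Irf4, which activated T cells also express, at 61.3 ± 20 TPM, and Ighm, the immunoglobulin M constant gene, at 46.4 ± 14.6 TPM with 204, 98 and 185 counts. Ctss stood at 18.9 ± 8.29 TPM, Cd74, which serves antigen presentation, at 15.8 ± 5.28 and Cd79a, part of the B cell receptor, at 7.34 ± 0.653. Of the pair of CD8 genes, Cd8a had 1 count in each library and Cd8b1 stood at 10.4 ± 2.64 TPM.

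In all, 11401 genes were detected at 1 TPM or more in every library, of which 8958 were protein-coding, 939 antisense and 276 lincRNA genes, and at 5 TPM or more the number was 7094. Mitochondrial genes took 4.71% ± 0.638 of the TPM, with mt-Nd6 alone at 2.52% ± 0.416. Ribosomal protein genes took 3.9% ± 0.668, replication-dependent histone genes, whose mRNAs lack polyA tails, 0.0189% ± 0.00185, and the 10 most abundant genes 12.3% ± 1.13. As shares of counts rather than TPM, mitochondrial genes held 1.27% ± 0.143 and the 10 genes 4.7% ± 0.787. All these shares are of counts on the annotated strand. They measure the composition of the RNA only if the strand option matched the library. The list of abundant nuclear and small noncoding RNA had 5 of 15 members detected (0.265 ± 0.172 TPM, percentile 44.3), with Gas5 at 61.5 ± 18.5 TPM and Malat1 at 22.8 ± 4.75 TPM (opposite Gm37376).

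T cell receptor V segments were spread over many genes, as far as the few counts show. Trbv segments had 241, 121 and 207 counts over 22 segments, and 9 segments held more than 5% each. The highest share was Trbv13-2 at 16.6% ± 6.36, with 12.9% (95% exact binomial interval 8.91 to 17.8), 24% (16.7 to 32.6) and 13% (8.77 to 18.4) in replicates 1, 2 and 3. Trbv2 followed at 10.5% ± 0.964, Trbv13-1 at 10.3% ± 2.23, Trbv1 at 9.75% ± 1.75, Trbv19 at 8.26% ± 3.33, Trbv31 at 7.8% ± 3.22, Trbv15 at 6.39% ± 1.27, Trbv3 at 6% ± 3.59 and Trbv16 at 5.63% ± 0.862. Trav segments had 151, 100 and 134 counts over 60 segments, with Trav13n-3 at 13.1% ± 3.05 (opposite Gm43650), Trav13d-3 at 7.23% ± 5.86 (opposite Gm30214) and Trav9-2 at 5.62% ± 3.19. How read pairs that match several near-identical segments were counted was not measured here, so the split between such segments is uncertain.

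Sex-linked genes separated the 3 libraries. The summed count of the 4 counted Y-linked genes was 165, 2 and 242, made of Ddx3y (59, 0 and 85), Eif2s3y (58, 1 and 77), Kdm5d (33, 1 and 56) and Uty (15, 0 and 24), while Usp9y and Zfy1 had 0 counts in each. Tsix (chromosome X, 103431517 to 103484957), which lies opposite Xist, the RNA that silences an X chromosome in female cells, had 1695, 5124 and 6 counts, and Xist (103460375 to 103483217) had 444, 510 and 1. Replicate 2 thus had Tsix and Xist with 2 Y-linked counts, replicate 3 the reverse, and replicate 1 both. Replicates 2 and 3 were therefore not technical repeats of 1 sample. The labels give the sex as not collected. With the strand option set against the library, the counts on Tsix may be of Xist RNA. The sex-linked list had a median of 1.5 ± 1.84 TPM at percentile 59.2 and no member detected in every library.

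**Figure D3:**
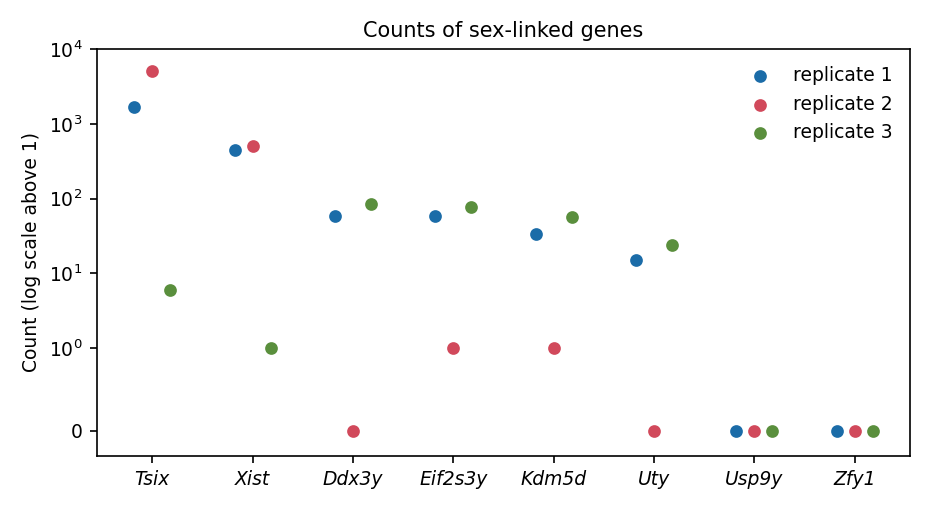
Points give the counts of the 8 sex-linked genes in each library (colours), on an axis that is logarithmic above 1. Tsix and Xist stand at 5124 and 510 counts in replicate 2 and at 6 and 1 in replicate 3, and Ddx3y at 0 and 85.

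Over all genes, replicate 2 stood apart from the other libraries. Across genes, Pearson's r of log2(TPM + 1) was 0.948 for replicates 1 and 2, 0.959 for 1 and 3 and 0.956 for 2 and 3, with Spearman's rho of 0.896, 0.912 and 0.901, where genes are not independent replicates. The chi-square of the counts per degree of freedom was 13.65, 3.85 and 7.8 for these pairs, a measure that sets biological replicates against counting noise alone. Of 10216 genes tested, 3642 (35.6%) varied beyond counting error in the chi-square test with Benjamini-Hochberg adjustment. By class, 2313 of 4362 overlapped, 238 of 1058 spanned, 502 of 2313 near and 589 of 2483 isolated genes varied. With TMM factors over all genes, replicate 2 was the highest library for 1997 of those overlapped genes and the lowest for 241, and the lowest for 453 of those isolated genes and the highest for 63. With DESeq2's size factors these numbers were 2050, 198, 394 and 73, and with total counts alone 1116, 930, 1344 and 10, so that the balance among overlapped genes depended on the scaling. Scaling each class within itself removes a shift that the class shares, so what is left is relative to the class: replicate 2 was the highest for 149 and the lowest for 41 of 219 varying isolated genes, and the highest for 829 and the lowest for 1041 of 2015 varying overlapped genes. Without replicate 2 the number was 971, and the biological coefficient of variation, 0.179 with all libraries, was 0.103. Scaling a class within itself was an alternative added after the values were seen. Then 219 of 2577 isolated genes (8.5%) and 2015 of 4348 overlapped genes (46.3%) varied, and the coefficient was 0.107 for isolated genes. For isolated genes it was 0.0845 without replicate 1, 0.0875 without replicate 2 and 0.142 without replicate 3. Leaving out replicate 1 thus lowered it as much as leaving out replicate 2 did.

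Among the 15 protein-coding genes with the widest ratios under TMM factors over all genes, most were lowest in replicate 1 and highest in replicate 2. The GTPase-like gene Arl5c (ENSMUSG00000038352, chromosome 11, 97989578 to 97996181, isolated) had 107, 282 and 303 counts, a ratio of 4.15 between the highest and lowest normalized counts (chi-square test, adjusted p = 5.84e-39). Gm5148 (opposite Rps23-ps1) had 571, 1325 and 925 counts, a ratio of 3.65. Sult1a1 (opposite Sgf29) reached the highest ratio, 5.11, on 16, 52 and 46 counts.

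Of 20 T cell identity genes 10 varied with TMM factors over all genes, or 11 adjusted over the list alone, and none of the 9 isolated ones varied when scaled among isolated genes. The SD between libraries of that list's mean log2 CPM was 0.117 over its 20 members and 0.019 over its 9 isolated members scaled among isolated genes. Of 17 early activation genes 13 varied, or 14 adjusted over the list alone, and 2 of 9 isolated ones scaled among isolated genes. Glycolysis had 11 of 18 varying by either adjustment, S phase 11 of 20 and nuclear oxidative phosphorylation 8 of 24, against 1 of 5, 1 of 6 and 1 of 3 isolated genes scaled among isolated genes. In the Th1 list 2 of 14 tested genes varied by either adjustment, in the Treg list 5 of 11 and in the Tfh list 6 of 8. As whole lists, none of 27 varied between libraries more than random lists matched on level (permutation against random lists, smallest adjusted p = 0.0513, 6 lists at an unadjusted p under 0.05), and with DESeq2's size factors the number was also 0. Cholesterol synthesis and p53 targets came closest, with deviations of 0.22, -0.19 and -0.03, and of 0.18, -0.27 and 0.09, from their mean log2 CPM. Over their isolated members, scaled among isolated genes, the deviations were 0.18, -0.06 and -0.12 for cholesterol synthesis (permutation against random lists, adjusted p = 0.485) and 0.06, -0.21 and 0.15 for p53 targets (permutation, adjusted p = 0.0864). The Treg list came closest there, with -0.28, 0.22 and 0.06 over 5 isolated members (permutation, adjusted p = 0.0768), against -0.03, 0.00 and 0.04 over all 11 tested members. Without replicate 2, early activation, cytokines and cholesterol synthesis passed (permutation against random lists, adjusted p = 0.0279 each).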

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

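The alternatives that use strand classes (isolated or overlapped genes), and those for the direction of replicate 2, were chosen after the data were examined; the others were fixed before. No paired analysis was possible because there is 1 group only. The alternative with posterior mean TPM was not run. The log2 ratios of Tbx21 kept their direction under every alternative run. They moved by more than 1 SD without length normalization (-1.32 to Gata3, -5.94 to Foxp3 and 0.73 to Bcl6), with a pseudocount of 0.1 (-5.58 to Foxp3 and 2.23 to Bcl6) and with FPKM (0.92 to Bcl6). Of the 40 alternative values of the 4 list differences, 34 kept their direction and their side of the threshold. The Th1 minus Th17 difference passed with a pseudocount of 0.1 (4.24), and among members at 1 TPM or more in at least 1 library it turned to -0.06. The Th1 minus Th2 difference turned to -0.60 among those members, and to -0.60 without the 5 lineage factors and the cytokines. The Th1 minus Tfh difference was 0.08 with means and ranged from -0.21 to 0.00 with 1 library left out, but was -1.94 without the lineage factors and cytokines, -1.59 without overlapped genes, -1.43 among isolated genes and -0.70 among members at 1 TPM or more. The Th1 minus Treg difference was -1.59, -1.41, -2.22 and -0.39 in the same order. None of the reversed values passed the test, and the cause was not tested. Against detected protein-coding genes, 10 lists stayed in the highest 2.5% instead of 17, which follows from a background without unexpressed genes. The percentile was then 0 for Th1, Th2, Th17, cytokines, chemokine receptors, cytotoxic granule, interferon response, sex-linked and abundant noncoding RNA genes and the 11 other cell lists ranked, 0.3 for Tfh, 0.2 for hypoxia and 8.8 for Treg. Among isolated genes it was 11 of 33 lists, and 30 of the 33 kept their side. With means in place of medians 30 of 39 lists kept their side, and leaving out each library in turn moved none of the 39 across either limit. The number of detected genes was 7094 at 5 TPM. Varying genes numbered 2399 with a fold of 1.5 or more required, 219 of 2577 isolated and 2015 of 4348 overlapped genes where each class was scaled within itself, which changed both genes and scaling (the cause was not tested), and from 971 to 3795 with 1 library left out, the lowest without replicate 2. Replicate 2 was then lowest for 41 isolated genes instead of 453 and highest for 829 overlapped genes instead of 1997, but this scaling removes a shift shared by the class by construction, so these counts say nothing of that shift. With total counts alone replicate 2 was highest for 1116 overlapped genes and lowest for 930. The coefficient of variation ranged from 0.103 to 0.238 with 1 library left out and was 0.107 among isolated genes. Lists varying between libraries numbered from 0 to 3 with 1 library left out. As shares of counts, mitochondrial genes held 1.27% and the 10 most abundant genes 4.7%. The numbers of receptor segments above 5% stayed within 1.5 times under each of their alternatives. Ifng, Il4, Tbx21 and the receptor segments rest on few counts, and whether depth or the strand counted sets that was not tested.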

Other observations

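All tests in this part, and the genes named here outside the fixed rule, were chosen after the results were seen, and with 1 group no biological explanation was tested. Genes on the opposite strand of list members often had more counts than the list members. Of 78 list genes with a gene on the opposite strand that overlaps no other gene and shares at least 100 exon bases, 50 had an opposite gene with 100 counts or more. Opposite Cd3e, a T cell receptor complex gene, Gm48719 had 2961, 2674 and 2758 counts where Cd3e averaged 160. Opposite Skap1, an adaptor gene, 2010300F17Rik had 1244, 1206 and 1231. Opposite Tnfrsf18, which encodes the costimulatory receptor GITR, Gm16008 had 5898, 5603 and 5926, opposite Bach2, Bach2os had 2350, 2102 and 2085, and opposite Bhlhe40, 0610040F04Rik had 2442, 2137 and 2034. Among genes of the lineage factors, Gm13256 opposite Gata3 had 225, 175 and 199 counts, while Ccdc22 opposite Foxp3 had 57, 52 and 50, far under the 900, 829 and 907 counts on Foxp3 itself. Opposite Csf1r, Hmgxb3 had 159, 70 and 129 counts against 1429, 1418 and 1460 on Csf1r.

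Isolated genes, which have no opposite-strand gene within 5000 bases, varied between replicates for 219 of 2577 genes once scaled among themselves, with replicate 2 highest for 149 and lowest for 41. Prpf38b, a splicing factor gene, had 1221, 1425 and 1658 counts, or 958.6, 2145.4 and 1561.1 when normalized (chi-square test, adjusted p = 7.77e-95), and Ptma had 3018.7, 5820.5 and 5413.9 normalized counts (chi-square test, adjusted p = 1.63e-231). Arl5c had 84, 424.6 and 285.3 normalized counts, lowest in replicate 1 and 5.05 times as high in replicate 2 (chi-square test, adjusted p = 2.69e-50). Kdm5c, an X-linked gene that escapes silencing, had 291, 237 and 208 counts, or 228.5, 356.8 and 195.8 when normalized (chi-square test, adjusted p = 7.76e-09). The scaling raised replicate 2, since isolated genes had 20.7, 12.3 and 18.4 counts per 100 on overlapped genes. As raw counts Kdm5c was highest in replicate 1, and Prpf38b, Ptma and Arl5c in replicate 3. Which library was highest for these genes thus depends on the scale.

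The first pattern is that the highest counts lay on overlapped genes. A candidate explanation is that the library marked strand and the counting used the opposite setting, which needs mt-Nd6 above the mitochondrial mRNAs of the other strand, and it was at least 15.1 times every one of them per kb in each library. For a library that does not mark strand, the opposite gene was taken to be the higher in a minority of list genes. It was the higher for 71.2% of 59 list genes with 100 counts on either side (95% exact binomial interval 57.9 to 82.2). That share cannot decide the question, because an opposite gene can also have more transcripts of its own. Abundant antisense transcripts counted on their own strand need the ratio of mt-Nd6 to the other mitochondrial mRNAs below 1. That ratio argues against them in the mitochondrial genome only, and for nuclear genes they were not tested. In a library that does not mark strand, each gene keeps part of its own mRNA's read pairs, so that ratio should lie below 1 as well. The ratio of at least 15.1, with 6 of the other 12 mitochondrial mRNAs at 3 counts or fewer in every library, argues against it there. If the counting used the opposite setting, counts on an overlapped gene read its partner's mRNA and those on Foxp3 may be of Ccdc22. Counts on isolated genes would then be a residue of their own mRNA.

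The second pattern is that isolated genes were lower in replicate 2. Per 100 counts on overlapped genes, isolated genes had 20.7, 12.3 and 18.4, and 876 of 894 isolated genes with a mean of 100 counts or more were lowest in replicate 2 at that scale. In 188 pairs of opposite-strand genes whose counts differ at least 5-fold, the lower-count gene fell further in replicate 2 than its partner in 183 (exact sign test across pairs, p = 9.72e-48). The pairs come from the same libraries and the contrast rests on replicate 2 alone, so this p-value does not measure a spread between libraries. A smaller share of read pairs on the unintended strand in replicate 2 would give such a fall. The median ratio of replicate 2 to the mean of the others was 0.645 for the lower-count and 1.05 for the higher-count genes. Counts were scaled to overlapped counts, which keeps the higher-count median near 1 by construction. The gap between the 2 medians counts against lower transcript levels only if the higher-count gene reads its partner's mRNA, and that was not tested pair by pair. Lower transcript levels thus cannot be told apart from that share for the pairs, nor for isolated genes, with a median ratio of 0.596, which no opposite-strand gene reads a second time.

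The third pattern is that replicate 1 had both Tsix and Y-linked counts. A small share of read pairs assigned to the wrong library is argued against, since relative to replicate 2 its Tsix level, scaled to overlapped counts, was 0.313 (95% Poisson interval 0.296 to 0.33) and relative to replicate 3 its Y-linked level, scaled to isolated counts, was 0.594 (0.486 to 0.721), both far above the 5% set for it. A candidate explanation is that cells of female and of male mice were together in replicate 1, which needs the levels to add up to about 1, and their sum was 0.906 (0.796 to 1.03). With Xist in place of Tsix the level was 0.488 scaled to isolated counts and 0.823 scaled to overlapped counts, and the sum 1.08 (0.958 to 1.23) and 1.42 (1.27 to 1.58), of which the last leaves out 1. The sum thus cannot tell a mixture from a difference between the mice in the level of these genes. It depends on the gene and the scale, and which scale applies was not measured. With the strand option set against the library, counts on Tsix may be of Xist RNA and those on Xist a residue of it. They would then not be separate measures. The scale for Xist would be that of isolated counts, where the interval of the sum, 0.958 to 1.23, holds 1. A difference in level alone would also have to give both kinds of counts in a single library. Neither replicate 2, with 2 Y-linked counts, nor replicate 3, with 6 Tsix counts and 1 Xist count, had both, though each is a single library.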
